A study of Homo sapiens with 11 samples.

How the data were processed

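Polyadenylated RNA of HCT116 cells was measured by sequencing in 11 libraries: 3 with DMSO, 4 with GTEA1 and 4 with GTEA7, each after 48 h. Per the labels, RNA was extracted with TRIzol, libraries were made with a NEBNext Ultra kit and random hexamer primers, and an Illumina NovaSeq was used. The deposited table holds raw read counts per gene, with 1 column per library, all of which were used. Most of its genes carry Ensembl IDs. The other IDs took 0.727% of all counts, and 659 of them were tested. The submitters' notes name STAR, Picard, SAMtools 0.1.18, GATK, HTSeq 0.5.4 and DESeq 1.10.1 without saying what each did. Genome build, annotation, counting options and strand setting are not given in the sources used here, so no coordinates are given. Symbols for 60370 of the Ensembl IDs came from a table of gene names, and GC content and length from GENCODE v29 transcripts. A symbol held by several IDs stands for the ID with the most counts.

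Each library was assigned to its group from the labels. All were labelled as the same batch, and replicate numbers are not said to mark a shared culture or day. Total counts were 16243886, 17431515 and 13866350 in DMSO replicates 1 to 3, then 13742326, 14426558, 16402162 and 16433111 in GTEA1 replicates 1 to 4, and 16976606, 19304211, 16772238 and 14955685 in GTEA7 replicates 1 to 4. Genes with enough counts were chosen by filterByExpr of edgeR with the groups as the design, which left 17963. TMM factors scaled the libraries, also for CPM. A single model of all 11 libraries was fitted with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood, robust), and the comparisons were tested by its F test. A gene passed at a Benjamini-Hochberg adjusted p under 0.05. Standard errors were derived from the log2 fold change and its F. Where a group had 0 counts throughout, a bound was computed from 3 counts over the group. Where it had 1 to 3, the ratio of pooled CPM is given with a 95% Clopper-Pearson interval. Bounds and intervals cover counting error only.

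For gene groups, 35 lists were fixed before the data were examined. They cover stem cell and pluripotency markers, Wnt, Notch, TGF-beta, YAP/TAZ, ERK, NF-kappaB and interferon genes, adhesion and mesenchymal genes, cell cycle, p53 and apoptosis genes, stress responses, lipid and energy metabolism, ribosomes, xenobiotic response, differentiation, histones and markers of other cell types. Each was tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the 35 lists. Beside it stand camera with an estimated correlation and fry, a rotation test of each list by itself. Counts of members that passed are given over all genes and adjusted over the list alone.

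The genes named follow a rule fixed before the data were examined. Per extract against DMSO they are the 8 largest rises and 8 largest falls among genes that passed, had a mean of at least 1 CPM over all 11 libraries and had every treated library on 1 side of every DMSO library. For GTEA7 against GTEA1 the numbers are 6 and 6. To these are added up to 4 members per list with the smallest adjusted p, 16 genes of interest whatever their values, and members of a list where 5 or fewer are counted. Not every eligible list member is named, and which to name was chosen after their values were seen, as were the pseudogenes and antisense genes named beside their partners.

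The changes of both extracts share the DMSO libraries, so their correlation across genes was set beside 20 simulated data sets with no effect. The method was also tested on simulated data with known changes. Of the changed genes, 59.7% were found at 1.25-fold, the smallest change simulated, in either comparison. At 1.5-fold it was 82.1% and 88.1% for GTEA1 and GTEA7, and at 2-fold 97% in both. Only genes above a floor of expected counts were changed, so these shares do not cover genes with few counts. False calls were 10 of 17229 genes and 7 of 17262, and false list calls 1 and 0 of 35. With the NRF2 target list raised it was called in both, and 1 and 2 other lists were called too. In these simulations genes were drawn independently of each other and few were changed. They therefore do not give the false list calls where members of a list vary together. Nor do they give the false calls where most genes change.

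The alternatives tried were DESeq2 size factors, library size as the only scaling, no low-count filter, a stricter one of at least 1 CPM in at least 3 libraries, the replicate number as a block, a fit of only the compared groups, limma-voom, the Wald test of DESeq2 1.42.0, camera with an estimated correlation, fry, and leaving out each library in turn. Library size only for the gene lists was chosen after seeing the data. Every split of the compared libraries into groups of the same sizes was also fitted. Within groups of 4, a library was singled out by Dixon's test. Nothing in the deposited table was left out other than genes with too few counts.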

Results

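Polyadenylated RNA was sequenced from HCT116, an established human colorectal carcinoma line of epithelial cells that the labels describe as ras mutant. The cells had been kept for 48 h with 1 of 2 triterpenoid extracts of Ganoderma, a genus of medicinal bracket fungi, or with the solvent DMSO as the control. The extracts are known by code names and are called here by their group names, GTEA1 and GTEA7. The title of the series states the question: how such extracts act on stemness and migration of colon cancer cells. There were 3 DMSO, 4 GTEA1 and 4 GTEA7 libraries, all labelled as batch 1, and no doses were given. Total counts per library ranged from 13866350 to 17431515 in DMSO, from 13742326 to 16433111 in GTEA1 and from 14955685 to 19304211 in GTEA7. In all, 17963 genes had enough counts to be tested. Below, a value after ± is a standard error for a log2 fold change and an SD for CPM (counts scaled for library size and TMM factor), with n = 3 for DMSO and n = 4 for each extract. Genes were tested with edgeR and gene lists with camera, and p-values are adjusted. Nothing in the labels says that the replicates were separate cultures. The p-values of genes therefore measure only the spread between these samples, whatever it came from. Those of camera set the members of a list against the other genes, at a small preset correlation between members. They treat the members as nearly independent and can be far smaller than with an estimated correlation. The limit on the replicates holds for them too.

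The first principal component of log2 CPM held 77.4% of the variance and set the GTEA1 libraries apart from all others. The second held 4.9% and separated GTEA7 from DMSO. The share of counts in mitochondrially encoded genes was 14.46% ± 0.96 (SD, n = 3) in DMSO, 13.12% ± 0.45 (SD, n = 4) in GTEA1 and 15.05% ± 0.15 (SD, n = 4) in GTEA7. Rows with IDs outside Ensembl took 0.548% ± 0.027 of the counts in DMSO (SD, n = 3), 1.076% ± 0.04 in GTEA1 and 0.539% ± 0.028 in GTEA7 (SD, n = 4 each). A single such ID, picked after its values were seen, went from 1850 ± 200 CPM in DMSO to 8380 ± 370 in GTEA1 and was at 2030 ± 180 in GTEA7. Its rise was at least as large as that of all these IDs together, so it accounts for their higher share in GTEA1.

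**Figure D1:**
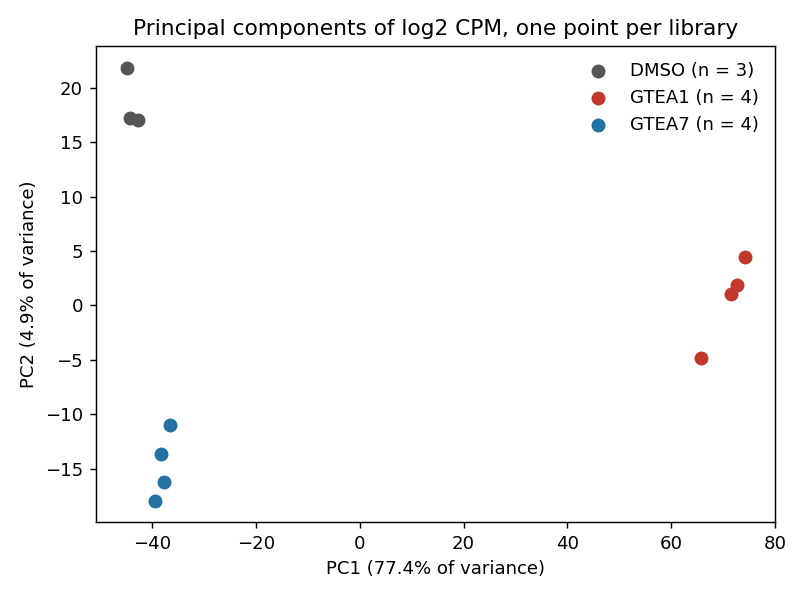
Principal components of log2 CPM with 1 point per library; the horizontal axis is the first component (77.4% of the variance) and the vertical axis the second (4.9%). The 4 GTEA1 libraries lie between 65.8 and 74.15 on the first component, and all DMSO and GTEA7 libraries lie below 0.

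The first comparison, GTEA1 against DMSO, asked what this extract changed in the cells. Of 29 ATF4 and amino acid response genes and of 29 NRF2 target genes, 26 each rose (adjusted p = 6.9e-66 and 1.3e-30). DDIT3 (ENSG00000175197), which encodes the stress transcription factor CHOP, rose 40.6-fold, from 3.32 ± 0.31 to 135 ± 13 CPM (log2 fold change 5.34 ± 0.09, adjusted p = 9.9e-29). HMOX1 (ENSG00000100292), the inducible heme oxygenase, rose 13.6-fold, from 15.5 ± 1.3 to 209 ± 9.3 CPM (adjusted p = 6.6e-47). Cell cycle genes and Wnt target genes fell: KIF20A (ENSG00000112984), a mitotic kinesin, went from 74.7 ± 1.4 to 13 ± 1.6 CPM (adjusted p = 4.2e-36), and AXIN2 (ENSG00000168646), a feedback inhibitor of Wnt signalling, from 60.3 ± 4.5 to 5.88 ± 0.97 CPM (adjusted p = 2.6e-38). In all, 12895 of the 17963 tested genes (71.8%) passed the test, 6390 higher and 6505 lower, and 1538 were higher and 2230 lower by at least 2-fold. With library size as the only scaling, the median log2 fold change of all genes was -0.167, and 4828 genes were higher and 8179 lower. Of the 35 lists, 23 passed camera's test, 15 higher and 8 lower, and 12 of these kept the call with an estimated correlation. Their adjusted p was then larger, from 0.00016 (NRF2 target genes) to 0.034 (DNA replication and G1/S genes). In this comparison, each count of members given below was the same when adjusted over the list alone.

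Among the largest rises was MMP1 (ENSG00000196611), the interstitial collagenase, at 5.49 ± 0.37 CPM in GTEA1. DMSO had 1 count over the group (0.023 ± 0.04 CPM), and the fitted log2 fold change of MMP1, 7.63 ± 0.4, rests on that read. The ratio of pooled CPM was 276, with a 95% counting interval (Clopper-Pearson) of 49.2 to 10900. The long noncoding RNA LINC01564 (6.62 ± 0.25), SPX (5.71 ± 0.23), which encodes the peptide hormone spexin, CHAC1 (5.34 ± 0.12), a glutathione-degrading enzyme, LURAP1L (4.93 ± 0.16), SLC7A11-AS1 (4.80 ± 0.19) and UPP1 (4.71 ± 0.08), a uridine phosphorylase, completed the 8 largest. SLC7A11-AS1 and LURAP1L each have an antisense partner that also rose, SLC7A11 (3.52 ± 0.05) and LURAP1L-AS1 (4.40 ± 0.37), and without a stated strand setting their counts are uncertain. The largest falls were in ATOH8 (ENSG00000168874), a basic helix-loop-helix transcription factor (-6.25 ± 0.38, with 3 counts over the GTEA1 group, and a pooled ratio of 86.9 with a 95% counting interval of 29.4 to 425), GJA1, the gap junction protein connexin 43 (-4.73 ± 0.22), SAMD15 (-4.53 ± 0.43), the chemokine receptor CXCR4 (-4.51 ± 0.21), FAM111B (-4.49 ± 0.12), the immune checkpoint ligand VTCN1 (-4.41 ± 0.44), the neural cell adhesion molecule NCAM1 (-4.41 ± 0.2) and ZCCHC12 (-4.40 ± 0.24). VTCN1 and SAMD15 had only 0.072 ± 0.06 and 0.0865 ± 0.1 CPM in GTEA1, so their fold changes rest on few reads. Every GTEA1 library lay beyond every DMSO library for each of these 16 genes, as the rule for naming them required.

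Of 29 tested ATF4 and amino acid response genes, 26 rose and 1 fell, with a median log2 fold change of 2.03 (adjusted p = 6.9e-66). They included TRIB3, a stress pseudokinase (3.75 ± 0.05), the cystine transporter SLC7A11 (3.52 ± 0.05), the alanyl-tRNA synthetase AARS1 (2.56 ± 0.04) and the amino acid transporter SLC7A5 (2.29 ± 0.04). The member that fell was SHMT2 (-0.21 ± 0.04), a serine hydroxymethyltransferase. Of 29 NRF2 target genes, 26 rose and 2 fell, with a median of 1.20 (adjusted p = 1.3e-30). The ferritin chains FTH1 (3.37 ± 0.04) and FTL (3.04 ± 0.04) were among them, but their pseudogenes FTH1P8 (3.55 ± 0.16) and FTLP3 (3.10 ± 0.11) rose too, so the share of reads from each copy is uncertain. The exporter ABCC2 (-1.55 ± 0.03) and TALDO1 (-0.55 ± 0.04), an enzyme of the pentose phosphate pathway, fell. Of 23 endoplasmic reticulum chaperones and unfolded protein response genes, 22 rose and 1 fell, with a median of 0.72 (adjusted p = 8.4e-17), among them HERPUD1 (2.46 ± 0.05), DNAJB9 (2.19 ± 0.06), the stress sensor ATF6 (1.22 ± 0.04) and MANF (1.04 ± 0.04). CALR, the lectin chaperone calreticulin, was the member that fell (-0.09 ± 0.03). Without DMSO replicate 3 its value was -0.08, with an adjusted p of 0.092. All 5 tested members of the metallothionein list, which holds a zinc exporter as well, rose, with a median of 0.86 (adjusted p = 0.00041): MT1X (2.61 ± 0.14), MT2A (1.99 ± 0.05), MT1E (0.86 ± 0.06), MT1F (0.70 ± 0.2) and the exporter SLC30A1 (0.69 ± 0.05). The metallothioneins are close paralogs, so how reads divide between them is uncertain.

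Of 16 heat shock genes, 15 fell and 0 rose, with a median of -0.47 (adjusted p = 1.2e-05, and adjusted p = 0.1 with an estimated correlation). Examples were the cochaperone DNAJA1 (-1.25 ± 0.04) and the chaperone HSP90AA1 (-1.20 ± 0.04). Of 37 autophagy and lysosome genes, 20 rose and 12 fell, with a median of 0.21 (adjusted p = 0.0048). The lysosomal protease CTSL (2.53 ± 0.04), the autophagosome protein gene MAP1LC3B (1.73 ± 0.04) and the lysosomal cholesterol transporter NPC1 (1.67 ± 0.05) rose.

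The cell cycle lists fell almost throughout. All 32 tested G2/M and mitosis genes fell, with a median of -1.38 (adjusted p = 4.9e-35, and adjusted p = 0.03 with an estimated correlation). Among them were KIF20A (-2.53 ± 0.06), the kinesin KIF11 (-2.09 ± 0.05) and cyclin B1, CCNB1 (-1.75 ± 0.05). Of 34 DNA replication and G1/S genes, 33 fell and 1 rose, with a median of -1.75 (adjusted p = 1.9e-32, and adjusted p = 0.034 with an estimated correlation). The replication initiation factor MCM10 (-2.44 ± 0.07) and UHRF1 (-1.71 ± 0.05) fell, and cyclin E1, CCNE1, rose (0.43 ± 0.06). CDKN1A (ENSG00000124762), which encodes the cyclin-dependent kinase inhibitor p21, rose from 86 ± 3.2 to 357 ± 13 CPM (2.05 ± 0.04, adjusted p = 1.5e-41). Of 30 p53 target genes, 16 rose and 9 fell, with a median of 0.23 (adjusted p = 2.4e-07). The stress cytokine GDF15 (4.10 ± 0.04), the death receptor TNFRSF10B (2.30 ± 0.04) and GADD45A (2.26 ± 0.04) rose. Of 31 apoptosis regulators, which hold genes for and against cell death, 18 rose and 9 fell, with a median of 0.37 (adjusted p = 0.035, adjusted p = 0.12 with an estimated correlation and adjusted p = 0.057 with library size only).

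Genes tied to stemness did not move as 1 block. Of 19 tested intestinal and colon cancer stem cell markers, 5 rose and 12 fell, with a median of -0.40, and the list was not past the threshold (adjusted p = 0.16). Those that rose were the aldehyde dehydrogenase ALDH1A3 (2.31 ± 0.04), the adhesion molecule ALCAM (0.86 ± 0.04), EPCAM (0.62 ± 0.04), PROM1 (0.28 ± 0.05), which encodes CD133, and the transcription factor SOX9 (0.23 ± 0.04). With library size only, SOX9 was at 0.07 and not past the threshold. The hyaluronan receptor CD44 fell (-0.35 ± 0.03). LGR5 and ALDH1A1 had 23 and 59 counts in total over the 11 libraries and were not tested. Of 15 Wnt/beta-catenin target genes, 13 fell and 0 rose, with a median of -1.08 (adjusted p = 7.3e-10). CEMIP (-2.86 ± 0.06) and the Wnt inhibitors AXIN2 (-3.37 ± 0.08), NOTUM (-2.13 ± 0.1), RNF43 (-1.75 ± 0.06) and its relative ZNRF3 (-1.29 ± 0.06) were among those that fell. RNF43 and ZNRF3 are on the stem cell list as well. Of 9 pluripotency factors, 5 rose and 1 fell, with a median of 0.13 (adjusted p = 0.00019). The mean was -0.02, and the median was -0.027 with library size only. The chromatin proteins HMGA1 (2.58 ± 0.04) and HMGA2 (0.56 ± 0.04) and the transcription factors KLF4 (1.46 ± 0.06) and KLF5 (1.01 ± 0.04) rose. NES, which encodes the filament protein nestin, was at 0.12 ± 0.05 and turned to -0.04 with library size only. Its call was also lost without DMSO replicate 1 or 2 (adjusted p = 0.12 each), without GTEA1 replicate 1, 2 or 3 (adjusted p = 0.13, 0.06 and 0.097), with only these groups in the fit (adjusted p = 0.073), with limma-voom (adjusted p = 0.053) and with DESeq2's test (adjusted p = 0.093). The member that fell was SOX2, with 0.552 ± 0.16 CPM in DMSO and 0 counts in every GTEA1 library. Its log2 fold change was at most -3.4, as bounded by 3 counts over the GTEA1 group. MYC was at -0.06 ± 0.04 and not past the threshold (adjusted p = 0.12), but with library size only it was at -0.22 and passed.

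Adhesion and migration genes shifted in both directions. Of 31 focal adhesion, laminin and migration genes, 18 rose and 10 fell, with a median of 0.28 (adjusted p = 8.8e-08). The urokinase PLAU (3.12 ± 0.05), its receptor PLAUR (2.31 ± 0.05) and the integrin ITGA3 (1.90 ± 0.04) rose, while MMP7, another metalloproteinase, fell from 0.772 ± 0.087 to 0.0536 ± 0.036 CPM (3 counts over the GTEA1 group, and a pooled ratio of 14.9 with a 95% counting interval of 4.75 to 75.5). Of 17 mesenchymal and EMT genes, 10 rose and 3 fell, with a median of 0.48 (adjusted p = 0.04, and adjusted p = 0.23 with an estimated correlation). The receptor kinase AXL rose (2.04 ± 0.04), as did, at 2.02 ± 0.39 against 3.02 ± 0.12 CPM, VIM (0.58 ± 0.18). Fibronectin, FN1 (-2.76 ± 0.05), the matrix protein gene SPARC (-1.57 ± 0.17) and S100A4 (-1.32 ± 0.08) fell. SNAI2 was at 0.48 ± 0.3 (adjusted p = 0.15), and at 0.76 without DMSO replicate 3 (adjusted p = 0.049). The mesenchymal list was not past the threshold without DMSO replicate 1 (adjusted p = 0.077), DMSO replicate 2 (adjusted p = 0.064) or GTEA1 replicate 4 (adjusted p = 0.061). Its call was also lost under a stricter low-count filter (adjusted p = 0.056) and with the replicate number as a block (adjusted p = 0.051). Of 24 epithelial junction and adhesion genes, 12 rose and 8 fell, with a median of 0.19 (adjusted p = 0.16). CLDN7 rose (1.99 ± 0.06), the desmosomal cadherin DSC2 fell (-1.25 ± 0.04), and E-cadherin, CDH1, was at 0.16 ± 0.04 and at 0.00 with library size only.

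Among the signalling lists, 13 of 24 ERK pathway output genes rose and 6 fell, with a median of 0.47 (adjusted p = 9.7e-10). The transcription factor FOSL1 (3.39 ± 0.05), the growth factor AREG (2.05 ± 0.04) and the receptor EPHA2 (2.06 ± 0.04) rose. Of 18 NF-kappaB target and inflammatory genes, 11 rose and 1, NFKB1 (-0.43 ± 0.06), fell, with a median of 0.98 (adjusted p = 0.019, and adjusted p = 0.09 with an estimated correlation). The chemokine CXCL8 (3.29 ± 0.19), the iron-binding secreted protein LCN2 (4.01 ± 0.23) and NFKB2 (1.1 ± 0.04) rose. Of 23 interferon-stimulated genes, 3 rose and 14 fell, with a median of -0.58 (adjusted p = 0.017, and adjusted p = 0.06 with an estimated correlation), including the antiviral genes IFIT1 (-2.81 ± 0.12) and OAS3 (-2.44 ± 0.07). Of 16 Notch pathway genes, 3 rose and 9 fell, with a median of -0.42 (adjusted p = 0.035, and adjusted p = 0.23 with an estimated correlation). The ligands JAG1 (-1.02 ± 0.04) and JAG2 (-0.97 ± 0.05) fell, whereas those that rose, HEY1 (1.55 ± 0.27), HES4 (0.75 ± 0.08) and HES1 (0.37 ± 0.1), encode transcriptional repressors that are known targets of Notch. With library size only, HES1 was at 0.21 and not past the threshold. Of 22 YAP/TAZ target genes, 10 rose and 8 fell, with a median of 0.11 (adjusted p = 0.035, adjusted p = 0.23 with an estimated correlation and adjusted p = 0.067 with library size only, where the median was -0.048). The ectonucleotidase NT5E (2.42 ± 0.05) and GADD45B (2.89 ± 0.09) rose and the transcription factor TEAD1 fell (-1.01 ± 0.03). The 21 TGF-beta target genes did not pass (8 higher, 11 lower, median -0.52, adjusted p = 0.17). In that list the differentiation inhibitors ID2 (-2.43 ± 0.05) and ID3 (-2.92 ± 0.07) fell.

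In metabolism, 15 of 26 cholesterol synthesis and SREBP2 target genes rose and 5 fell, with a median of 0.63 (adjusted p = 0.00013, and adjusted p = 0.19 with an estimated correlation). The sterol oxidase MSMO1 (2.24 ± 0.04) and HMGCS1 (0.86 ± 0.05) rose, and lanosterol synthase, LSS, fell (-1.34 ± 0.07). ABCA1, a cholesterol exporter, fell from 11.8 ± 0.55 to 1.83 ± 0.14 CPM (-2.69 ± 0.14). Of 31 hypoxia and glycolysis genes, 25 fell and 3 rose, with a median of -1.08 (adjusted p = 6.2e-12, and adjusted p = 0.061 with an estimated correlation). The glucose transporter SLC2A1 (-1.88 ± 0.04), PGAM1 (-1.68 ± 0.04) and GPI (-1.32 ± 0.04) fell, and NDRG1 (2.02 ± 0.1), the angiogenic factor VEGFA (1.77 ± 0.04) and P4HA2 (0.72 ± 0.05) rose. CYP1A1, the classic target of the aryl hydrocarbon receptor, rose from 2.19 ± 0.13 to 6.8 ± 0.3 CPM (1.62 ± 0.14). The receptor's other targets AHRR (1.08 ± 0.28), TIPARP (2.03 ± 0.04) and NQO1 (1.37 ± 0.04) rose too, but the 13 xenobiotic response genes did not pass as a list (5 higher, 6 lower, median 0.22, adjusted p = 0.31). Of 43 cytosolic ribosomal protein genes, 39 rose and 1, RPS23 (-0.72 ± 0.05), fell, with a median of 0.35 (adjusted p = 9.6e-05, and adjusted p = 0.5 with an estimated correlation), and RPS12 rose (0.77 ± 0.04). Many pseudogene copies of such genes exist, and how reads divide between them is uncertain. Of 13 mitochondrially encoded genes, 9 fell and 2 rose, with a median of -0.76 (adjusted p = 0.019, and adjusted p = 0.47 with an estimated correlation). MT-CYB (-1.04 ± 0.04), MT-ATP6 (-0.79 ± 0.05) and MT-CO3 (-0.76 ± 0.04) fell, MT-CO1 rose (0.28 ± 0.04), and MT-ND4 (0.20 ± 0.05) was at 0.04 and not past the threshold with library size only.

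The other lists were not past the threshold in GTEA1. Of 34 ribosome biogenesis and MYC target genes, 5 rose and 19 fell (median -0.15, adjusted p = 0.065, and adjusted p = 0.01 with library size only). Of 18 fatty acid synthesis and SREBP1 target genes, 10 rose and 7 fell (median 0.16, adjusted p = 0.45), with ACSS2 (2.07 ± 0.04) and ME1 (1.32 ± 0.04) higher. Of 10 LXR target genes, 3 rose and 5 fell (median -0.15, adjusted p = 0.48), and ABCG1 (-0.70 ± 0.14) and MYLIP (-0.79 ± 0.07) were among those lower. Of 6 histone genes, whose messages mostly lack a poly(A) tail, H1-2 (1.49 ± 0.11) and H2AC6 (0.95 ± 0.1) rose and H2AC11 fell (-1.66 ± 0.34; median 0.40, adjusted p = 0.45). Of 7 enterocyte and goblet cell differentiation genes, 2 rose and 4 fell (median -0.50, adjusted p = 0.55), KRT20 (-1.76 ± 0.3) and CDX2 (-0.57 ± 0.09) among the latter. Nuclear-encoded oxidative phosphorylation genes split 10 higher and 11 lower of 34 (adjusted p = 0.91). The split of fatty acid oxidation and PPAR target genes was 5 and 5 of 16 (adjusted p = 0.91). Both medians were 0.03 while camera's direction was lower, and with library size only they were -0.133 and -0.13. Of the fibroblast, endothelial and blood cell markers, 6 were tested; KDR (1.23 ± 0.22) and ALAS2 (1.16 ± 0.28) rose and COL1A1 fell (-0.34 ± 0.06; median -0.26, adjusted p = 0.93).

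The second comparison, GTEA7 against DMSO, asked the same of the other extract. Of 26 cholesterol synthesis genes 23 rose, and of 18 fatty acid synthesis genes 13 rose (adjusted p = 1.8e-150 and 1.9e-47). HMGCS1 (ENSG00000112972), the synthase that leads into the mevalonate pathway, rose from 83.9 ± 2.6 to 235 ± 2.8 CPM (log2 fold change 1.48 ± 0.05, adjusted p = 1e-22). SCD (ENSG00000099194), a stearoyl-CoA desaturase, rose from 1530 ± 22 to 3380 ± 53 CPM (1.14 ± 0.04, adjusted p = 8.5e-29). SMAD7 (ENSG00000101665), the inhibitory SMAD of TGF-beta and BMP signalling, fell from 13.3 ± 0.53 to 3.44 ± 0.3 CPM (-1.95 ± 0.11, adjusted p = 2.7e-20), and ID3 (ENSG00000117318) from 59.1 ± 2.5 to 21.5 ± 1.8 CPM (-1.46 ± 0.06, adjusted p = 1.4e-26). In all, 4036 genes (22.5%) passed the test, 2159 higher and 1877 lower, with a median absolute log2 fold change of 0.23 among them. Only 53 were higher and 51 lower by at least 2-fold. That total changed by more than 1.5 times with no low-count filter and with DESeq2's test, as given further below. With library size as the only scaling, the median log2 fold change of all genes was -0.06, and 1255 genes were higher and 2954 lower. Of the 35 lists, 20 passed, 13 higher and 7 lower, and 9 of these kept the call with an estimated correlation. Their adjusted p was then larger, from 1.2e-05 (NRF2 target genes) to 0.044 (Notch pathway genes, and autophagy and lysosome genes).

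The 8 largest rises were LINC01564 (2.30 ± 0.51, from only 0.0981 ± 0.026 to 0.522 ± 0.083 CPM), the endothelial lipase LIPG (1.81 ± 0.08), the sterol sensor protein INSIG1 (1.66 ± 0.05), ALDH1A3 (1.56 ± 0.04), MSMO1 (1.50 ± 0.04), HMGCS1, the growth factor carrier FGFBP1 (1.47 ± 0.12) and the isopentenyl diphosphate isomerase IDI1 (1.41 ± 0.05). The 8 largest falls were ATOH8 (-1.99 ± 0.2), SAMD11 (-1.95 ± 0.13), SMAD7, the homeobox gene DLX2 (-1.81 ± 0.16), ID3, the Wnt inhibitor NOTUM (-1.32 ± 0.08), ABCA1 (-1.32 ± 0.11) and UTS2B (-1.31 ± 0.27). For each of these 16 genes every GTEA7 library lay beyond every DMSO library, again as the naming rule required.

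Of 26 cholesterol synthesis and SREBP2 target genes, 23 rose and 0 fell, with a median of 0.76 (adjusted p = 1.8e-150, and adjusted p = 2.6e-05 with an estimated correlation). Adjusted over the list alone, 23 were higher and 1 lower. The squalene epoxidase SQLE (1.00 ± 0.04) was among those that rose. Of 18 fatty acid synthesis and SREBP1 target genes, 13 rose and 2, ACACB (-0.30 ± 0.07) and SCD5 (-0.17 ± 0.05), fell, with a median of 0.50 (adjusted p = 1.9e-47; 14 higher and 3 lower adjusted over the list alone). The elongase ELOVL6 (0.96 ± 0.04) and the acetyl-CoA synthetase ACSS2 (0.87 ± 0.04) rose. Of 10 LXR target genes, SCD and SREBF1 (0.31 ± 0.04) rose and the exporters ABCA1 and ABCG1 (-0.97 ± 0.14) and the ubiquitin ligase MYLIP (-0.54 ± 0.07) fell. Their median was -0.03 (adjusted p = 0.52; 3 higher and 3 lower adjusted over the list alone), although camera's direction was higher. Of 16 fatty acid oxidation and PPAR target genes, 4 rose and 0 fell, with a median of 0.11 (adjusted p = 0.015, and adjusted p = 0.1 with an estimated correlation; 5 higher adjusted over the list alone), among them ACSL1 (0.42 ± 0.05) and PLIN2 (0.39 ± 0.06).

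Of 29 NRF2 target genes, 21 rose and 1, ABCC2 (-0.38 ± 0.03), fell, with a median of 0.49 (adjusted p = 1.3e-56; 23 higher and 1 lower adjusted over the list alone). SLC7A11 (1.36 ± 0.05), the quinone reductase NQO1 (0.92 ± 0.04), the malic enzyme ME1 (0.80 ± 0.04) and HMOX1 (0.58 ± 0.07) rose. FTL (0.91 ± 0.04) and its pseudogene FTLP3 (1.18 ± 0.14) rose together. Of 13 xenobiotic response genes, 7 rose and 2, ABCC2 and the receptor AHR (-0.39 ± 0.05), fell, with a median of 0.10 (adjusted p = 0.00014; the same counts adjusted over the list alone). CYP1A1 rose from 2.19 ± 0.13 to 5.8 ± 0.19 CPM (1.40 ± 0.14), and TIPARP rose by 0.67 ± 0.05 on the log2 scale. Of 29 ATF4 and amino acid response genes, 13 rose and 4 fell, with a median of 0.10 (adjusted p = 0.001, and adjusted p = 0.14 with an estimated correlation; the same counts adjusted over the list alone). The transporter subunit SLC3A2 (0.28 ± 0.04) and the glycyl-tRNA synthetase GARS1 (0.25 ± 0.04) rose, and the stress-induced inhibitors of mTORC1 signalling DDIT4 (-0.73 ± 0.1) and SESN2 (-0.66 ± 0.13) fell. DDIT3 was at -0.18 ± 0.18 and not past the threshold (adjusted p = 0.55). Of 23 endoplasmic reticulum chaperones and unfolded protein response genes, 11 rose and 0 fell, with a median of 0.12 (adjusted p = 0.0032, and adjusted p = 0.28 with an estimated correlation; 12 higher and 1 lower adjusted over the list alone). PDIA3 (0.16 ± 0.03) and XBP1 (0.22 ± 0.05) were among them. Of 16 heat shock genes, 8 rose and 0 fell, with a median of 0.11 (adjusted p = 0.0028, and adjusted p = 0.28 with an estimated correlation; 9 higher adjusted over the list alone), among them HSPD1 (0.26 ± 0.04) and HSPA8 (0.24 ± 0.04). Of 37 autophagy and lysosome genes, 13 rose and 4 fell, with a median of 0.07 (adjusted p = 0.0094; 14 higher and 5 lower adjusted over the list alone), with WIPI1 (0.44 ± 0.06) and NPC1 (0.36 ± 0.05) higher. The metallothionein list, with SLC30A1 as 1 of its 5 tested members, did not pass (1, MT1E at 0.19 ± 0.06, higher; 2 adjusted over the list alone; median 0.15, adjusted p = 0.46). The call of MT1E was lost without DMSO replicate 1 (adjusted p = 0.13), DMSO replicate 3 (adjusted p = 0.09) or GTEA7 replicate 2, 3 or 4 (adjusted p = 0.056, 0.054 and 0.051), and with library size only (adjusted p = 0.12).

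Of 21 TGF-beta target genes, 13 fell and 1 rose, with a median of -0.34 (adjusted p = 7.1e-21; the same counts adjusted over the list alone). ID2 (-0.92 ± 0.04) and ID1 (-0.40 ± 0.03) fell. Of 15 Wnt/beta-catenin target genes, 9 fell and 2, MYC (0.36 ± 0.03) and CD44 (0.10 ± 0.03), rose, with a median of -0.27 (adjusted p = 8.5e-08; 2 higher and 10 lower adjusted over the list alone). AXIN2 (-0.58 ± 0.05) and DKK1 (-0.42 ± 0.04), another secreted Wnt inhibitor, fell. The call of CD44 was lost without DMSO replicate 2 (adjusted p = 0.12), without DMSO replicate 3 (adjusted p = 0.08) and with library size only (adjusted p = 0.29). Of 16 Notch pathway genes, 6 fell and 0 rose, with a median of -0.18 (adjusted p = 2.6e-05; 7 lower adjusted over the list alone), among them JAG1 (-0.44 ± 0.04), the receptors NOTCH1 (-0.31 ± 0.05) and NOTCH3 (-0.30 ± 0.04) and HES1 (-0.78 ± 0.11). The 24 ERK pathway output genes went both ways (8 higher, 7 lower, the same adjusted over the list alone; median -0.03, adjusted p = 0.93). EREG rose (0.71 ± 0.04), and the feedback inhibitors SPRY4 (-0.49 ± 0.04) and DUSP6 (-0.45 ± 0.04) and EPHA2 (-0.50 ± 0.04) fell. YAP/TAZ target genes did not pass (3 higher and 6 lower of 22, or 3 and 7 adjusted over the list alone; median -0.13, adjusted p = 0.079), but did without DMSO replicate 2 (adjusted p = 0.043), without GTEA7 replicate 1 (adjusted p = 0.049) and with library size only (adjusted p = 0.037). In that list AMOTL2 fell (-0.82 ± 0.07) and NT5E rose (0.60 ± 0.05).

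Of 19 stem cell markers, 5 rose and 5 fell (6 and 5 adjusted over the list alone), with a median of -0.02 (adjusted p = 0.13), although camera's direction was higher. ALDH1A3 (1.56 ± 0.04), EPCAM (0.25 ± 0.04), PROM1 (0.18 ± 0.05) and CD44 were among those higher, and EPHB3 (-0.55 ± 0.09), LRIG1 (-0.40 ± 0.13), MEX3A (-0.38 ± 0.06), RNF43 (-0.27 ± 0.05) and ZNRF3 (-0.18 ± 0.05) were lower. The call of LRIG1 was lost without DMSO replicate 1 (adjusted p = 0.13), without GTEA7 replicate 3 (adjusted p = 0.087), with DESeq2's test (adjusted p = 0.11) and with no filter (adjusted p = 0.051). Of 9 pluripotency factors, HMGA1 (0.44 ± 0.04) and MYC rose and 0 fell, also adjusted over the list alone, with a median of 0.05 (adjusted p = 0.019, and adjusted p = 0.083 with an estimated correlation) that was -0.003 with library size only. SOX2 was at 0.17 ± 0.38 (adjusted p = 0.81). Of 17 mesenchymal and EMT genes, 6 fell and 1 rose, with a median of -0.21 (adjusted p = 0.001, and adjusted p = 0.07 with an estimated correlation; 1 higher and 7 lower adjusted over the list alone). FN1 (-0.60 ± 0.04), the fibronectin receptor chain ITGA5 (-0.24 ± 0.05) and the membrane metalloproteinase MMP14 (-0.28 ± 0.07) fell. VIM fell from 2.02 ± 0.39 to 1.32 ± 0.17 CPM (-0.61 ± 0.21), a call lost without DMSO replicate 1 (adjusted p = 0.21), without GTEA7 replicate 3 (adjusted p = 0.093), with DESeq2's test (adjusted p = 0.1) and with no filter (adjusted p = 0.07). Of 31 focal adhesion, laminin and migration genes, 6 fell and 2 rose, with a median of -0.05 (adjusted p = 0.014, and adjusted p = 0.052 with an estimated correlation; 3 higher and 7 lower adjusted over the list alone). The integrin ITGB4 (-0.52 ± 0.04) and the laminin chains LAMB3 (-0.44 ± 0.06) and LAMA5 (-0.30 ± 0.04) fell. Epithelial junction genes did not pass (7 higher and 3 lower of 24, also adjusted over the list alone; median 0.05, and -0.003 with library size only; adjusted p = 0.57), and CGN fell (-0.34 ± 0.05). CDH1 (-0.04 ± 0.04, adjusted p = 0.46), SNAI2 (-0.21 ± 0.32, adjusted p = 0.7) and MMP7 (-0.35 ± 0.32, adjusted p = 0.48) were not past the threshold.

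Of 34 ribosome biogenesis and MYC target genes, 23 rose and 0 fell, with a median of 0.20 (adjusted p = 1.4e-12; 26 higher and 1 lower adjusted over the list alone). The transferrin receptor TFRC (0.63 ± 0.03) and the nucleolar proteins NOLC1 (0.28 ± 0.03) and GNL3 (0.26 ± 0.03) rose. Of 43 cytosolic ribosomal protein genes, 7 rose and 0 fell, also adjusted over the list alone, with a median of 0.05 (adjusted p = 0.027, and adjusted p = 0.73 with an estimated correlation) that was -0.004 with library size only. RPL24 (0.17 ± 0.04) and RPS12 (0.17 ± 0.04) were among them. This call was lost without DMSO replicate 1 (adjusted p = 0.38), DMSO replicate 3 (adjusted p = 0.052), GTEA7 replicate 2 (adjusted p = 0.16) or GTEA7 replicate 3 (adjusted p = 0.073), and with library size only (adjusted p = 0.35). Of 34 nuclear-encoded oxidative phosphorylation genes, 11 rose and 0 fell, with a median of 0.08 (adjusted p = 0.0021, and adjusted p = 0.47 with an estimated correlation; 12 higher adjusted over the list alone), NDUFB5 (0.28 ± 0.05) and COX5A (0.23 ± 0.04) among them. Mitochondrially encoded genes did not pass (2 higher, 1 lower of 13, also adjusted over the list alone; median 0.07, adjusted p = 0.49), with MT-CO1 at 0.16 ± 0.04 (adjusted p = 0.056 without DMSO replicate 2) and MT-CYB at -0.22 ± 0.04. Of 31 hypoxia and glycolysis genes, 15 fell and 1, ALDOC (0.50 ± 0.07), rose, with a median of -0.14 (adjusted p = 5e-06, and adjusted p = 0.22 with an estimated correlation; 1 higher and 17 lower adjusted over the list alone). The peptide hormone gene ADM (-0.57 ± 0.05) and SLC2A1 (-0.24 ± 0.04) fell. Of 32 G2/M and mitosis genes, 12 fell and 1, BUB3 (0.13 ± 0.03, adjusted p = 0.089 with library size only), rose, also adjusted over the list alone, with a median of -0.10 (adjusted p = 0.0021, and adjusted p = 0.58 with an estimated correlation). KIF20A (-0.28 ± 0.05), TOP2A (-0.22 ± 0.05) and ANLN (-0.17 ± 0.04) fell.

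The remaining lists did not pass in GTEA7. DNA replication and G1/S genes had a median of 0.00 with 2 higher and 1 lower of 34 (1 and 1 adjusted over the list alone; adjusted p = 0.86). Those higher were RFC3 (0.23 ± 0.05) and SLBP (0.12 ± 0.04), and the call of SLBP was lost without any of 6 libraries (DMSO replicates 1 to 3 and GTEA7 replicates 1 to 3), with adjusted p from 0.062 to 0.084, and with library size only (adjusted p = 0.25). For p53 target genes 5 were higher and 10 lower of 30 (5 and 11 adjusted over the list alone; median -0.07, adjusted p = 0.13), with GDF15 at 0.48 ± 0.05 and BTG2 at -0.47 ± 0.06, and CDKN1A was at -0.01 ± 0.04 (adjusted p = 0.93). Apoptosis regulators had 7 higher and 5 lower of 31, also adjusted over the list alone (median 0.02, adjusted p = 0.58), with cytochrome c, CYCS, at 0.29 ± 0.03. Interferon-stimulated genes had 1 higher and 6 lower of 23 (2 and 6 adjusted over the list alone; median -0.01, adjusted p = 0.4), with IFI6 at -0.43 ± 0.09. NF-kappaB target genes had 2 higher and 1 lower of 18 (0 and 1 adjusted over the list alone; median 0.03, adjusted p = 0.9), with the inhibitor NFKBIA at -0.42 ± 0.07. Of 7 enterocyte and goblet cell differentiation genes 1, CA2 (0.19 ± 0.07), was higher (median 0.07, adjusted p = 0.66), a call lost without DMSO replicate 2 (adjusted p = 0.27), without GTEA7 replicate 1, 2 or 3 (adjusted p = 0.091, 0.072 and 0.1), with library size only (adjusted p = 0.13) and with DESeq2's test (adjusted p = 0.083). Of 6 histone genes 1, H2AC6 (-0.35 ± 0.12), was lower (median -0.16, adjusted p = 0.67), a call lost without DMSO replicate 1 (adjusted p = 0.14) or GTEA7 replicate 1 or 3 (adjusted p = 0.093 and 0.081), with no filter (adjusted p = 0.063) and with DESeq2's test (adjusted p = 0.084). Of 6 fibroblast, endothelial and blood cell markers 1, COL1A1 (-0.39 ± 0.06), was lower (median 0.30, adjusted p = 0.83), although camera's direction was lower. These 3 lists had the same counts adjusted over the list alone.

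**Figure D2:**
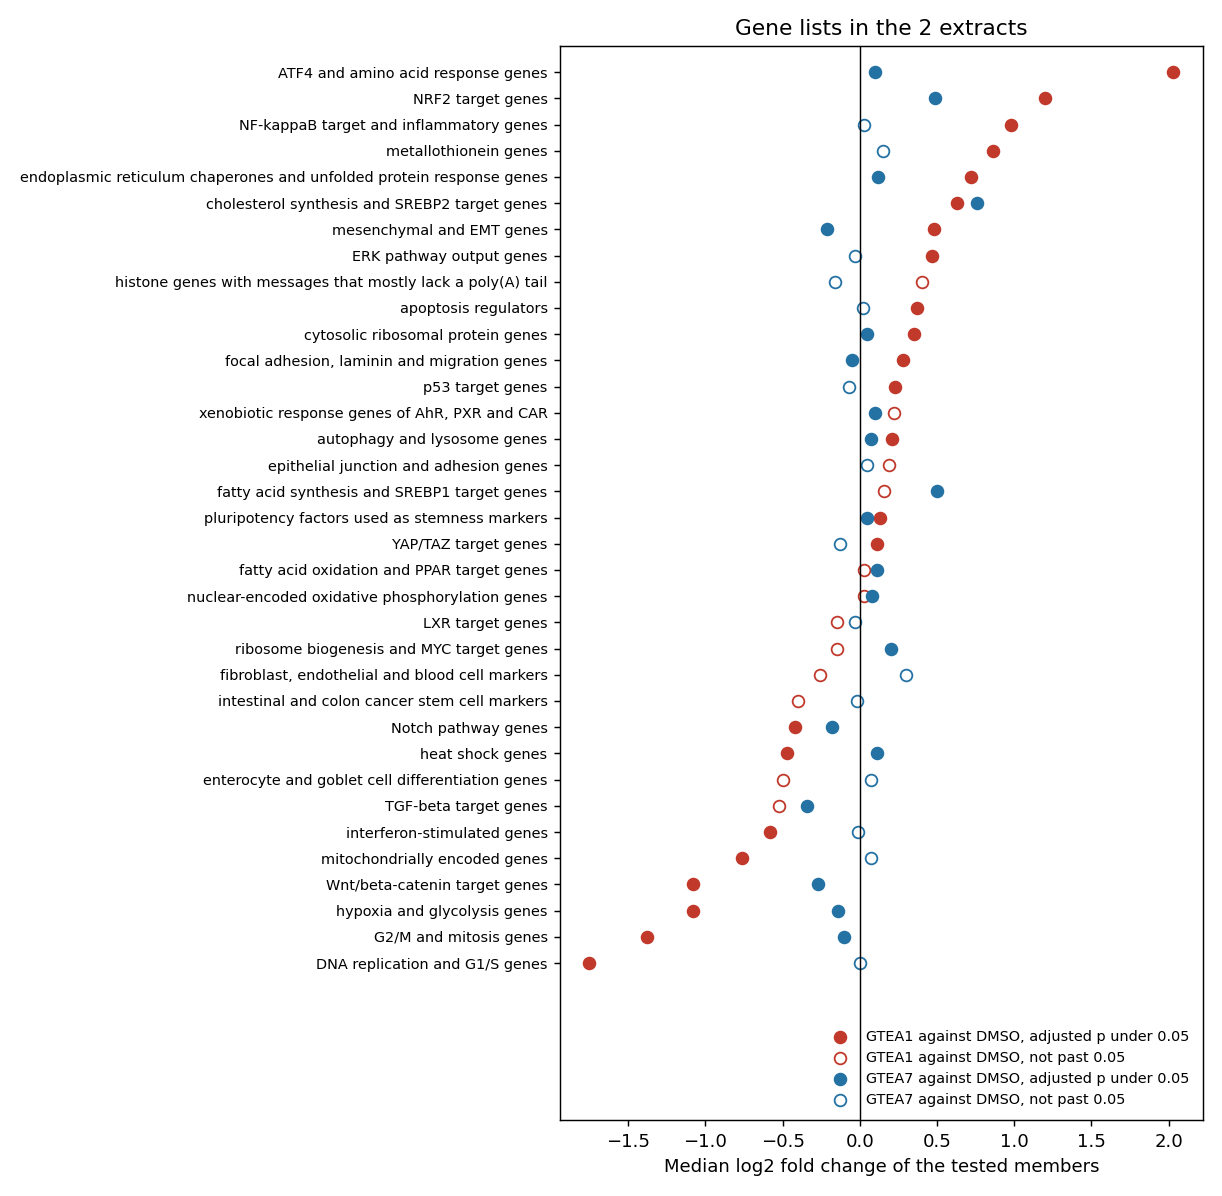
Median log2 fold change of the tested members of each of the 35 lists (horizontal axis) in GTEA1 against DMSO (red) and GTEA7 against DMSO (blue); filled points passed camera's test at an adjusted p under 0.05 and open points did not. The medians run from -1.75 to 2.03 in GTEA1 and from -0.34 to 0.76 in GTEA7.

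The third comparison, GTEA7 against GTEA1, tested where the extracts differed. No doses are given, so a difference here can be one of dose as well as of extract. The ATF4 and amino acid response genes were lower in GTEA7 than in GTEA1 in 26 of 29 cases (adjusted p = 1.8e-69), and DNA replication and G1/S genes higher in 33 of 34 (adjusted p = 1.4e-34). DDIT3 had 2.94 ± 0.43 CPM in GTEA7 and 135 ± 13 in GTEA1 (log2 fold change -5.52 ± 0.08, adjusted p = 3e-30), and FAM111B (ENSG00000189057) had 25.6 ± 1.5 CPM against 1.18 ± 0.2 (4.45 ± 0.12, adjusted p = 7e-36). In all, 13056 genes passed (72.7%), 6510 higher and 6546 lower in GTEA7, and 2006 were higher and 1548 lower by at least 2-fold. With library size only the split was 7653 higher and 5455 lower, and the median of all genes was 0.109. The largest differences also included MYB (4.32 ± 0.2), VTCN1 (4.29 ± 0.43), ATOH8 (4.26 ± 0.51, on 3 counts in GTEA1, with a 95% counting interval of the pooled ratio of 7.23 to 109), SAMD15 (4.09 ± 0.44) and METTL7A (4.04 ± 0.16), higher in GTEA7, and MMP1 (-6.39 ± 0.3), SPX (-5.39 ± 0.19), CHAC1 (-5.11 ± 0.1), UPP1 (-4.74 ± 0.07) and LMOD1 (-4.68 ± 0.11), lower. VTCN1 and SAMD15 had only 0.072 ± 0.06 and 0.0865 ± 0.1 CPM in GTEA1. MMP1 had 4 counts over the GTEA7 group (0.0584 ± 0.0059 CPM). These fold changes also rest on few reads. Of the 35 lists, 25 passed, 11 higher and 14 lower in GTEA7, and 11 of them kept the call with an estimated correlation. Their adjusted p was then larger, from 0.00019 (ATF4 and amino acid response genes) to 0.041 (both cell cycle lists).

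Those 11 lists were the following. The ATF4 and amino acid response genes (26 of 29 lower, median -1.85, adjusted p = 1.8e-69) included TRIB3 (-3.41 ± 0.04) and AARS1 (-2.43 ± 0.04). The NRF2 target genes (25 of 29 lower, 4 higher, median -0.72, adjusted p = 4.5e-16) included HMOX1 (-3.19 ± 0.05) and FTH1 (-2.73 ± 0.03). Of 23 endoplasmic reticulum genes 22 were lower (median -0.81, adjusted p = 1.3e-15), among them HERPUD1 (-2.34 ± 0.04) and DNAJB9 (-2.14 ± 0.05). DNA replication and G1/S genes were higher in 33 of 34 cases (median 1.80, adjusted p = 1.4e-34), with MCM10 at 2.45 ± 0.07. All 32 G2/M and mitosis genes were higher (median 1.32, adjusted p = 1.3e-32), with KIF11 at 1.95 ± 0.05 and CCNB1 at 1.79 ± 0.05. Wnt/beta-catenin target genes were higher in 14 of 15 cases (median 0.61, adjusted p = 7.5e-07), AXIN2 by 2.79 ± 0.08 and CEMIP by 2.57 ± 0.06. Of the ERK pathway output genes 16 of 24 were lower and 5 higher (median -0.47, adjusted p = 5.6e-11), and EPHA2 (-2.56 ± 0.04) and FOSL1 (-3.03 ± 0.05) were lower. Focal adhesion, laminin and migration genes were lower in 21 and higher in 9 of 31 cases (median -0.32, adjusted p = 7.3e-11), with PLAU at -3.12 ± 0.05. Of 30 p53 target genes 18 were lower and 6 higher (median -0.34, adjusted p = 1.1e-09), GDF15 by -3.62 ± 0.04. All 5 tested members of the metallothionein list, SLC30A1 (-0.63 ± 0.04) among them, were lower (median -1.1, adjusted p = 0.00049). Of 9 pluripotency factors 4 were lower and 2 higher (median -0.42, adjusted p = 8e-04; the mean was 0.09), with HMGA1 at -2.14 ± 0.03 and KLF4 at -1.58 ± 0.06. Adjusted over the list alone these 11 counts were the same.

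The other 14 calls were lost with an estimated correlation, whose adjusted p is given second here. Heat shock genes were higher in GTEA7 in 15 of 16 cases (median 0.58, adjusted p = 3.1e-08 and 0.063), HSP90AA1 by 1.34 ± 0.04 and DNAJA1 by 1.31 ± 0.04. Hypoxia and glycolysis genes were higher in 24 and lower in 4 of 31 cases (median 0.79, adjusted p = 7.7e-09 and 0.092), with SLC2A1 higher (1.64 ± 0.04) and VEGFA lower (-1.85 ± 0.04). Mesenchymal and EMT genes were lower in 12 and higher in 3 of 17 cases (median -0.69, adjusted p = 0.0012 and 0.086). AXL (-2.24 ± 0.04) was lower, and FN1 (2.16 ± 0.05), SPARC (1.26 ± 0.16) and S100A4 (1.13 ± 0.08) higher. Cholesterol synthesis genes were higher in 17 and lower in 4 of 26 cases (median 0.32, adjusted p = 0.0029 and 0.26), LSS (1.90 ± 0.06) higher and MSMO1 (-0.75 ± 0.03) lower. Fatty acid synthesis genes were higher in 11 and lower in 5 of 18 cases (median 0.41, adjusted p = 0.0029 and 0.089), with SCD at 1.38 ± 0.04 and ACSS2 at -1.21 ± 0.04. Ribosome biogenesis genes were higher in 26 and lower in 1 of 34 cases (27 and 1 adjusted over the list alone; median 0.29, adjusted p = 7.3e-05 and 0.089), with NCL at 0.91 ± 0.03 and NOP56 at 0.89 ± 0.03. Cytosolic ribosomal protein genes were lower in 38 and higher in 2 of 43 cases (median -0.29, adjusted p = 0.00066 and 0.51). The mitochondrially encoded genes were higher in 9 and lower in 2 of 13 cases (median 0.75, adjusted p = 0.0059 and 0.4), with MT-CYB at 0.81 ± 0.04. Of the YAP/TAZ target genes 12 of 22 were lower and 5 higher (13 and 6 adjusted over the list alone; median -0.17, adjusted p = 0.0044 and 0.11), with NT5E at -1.82 ± 0.04. NF-kappaB target genes were lower in 11 and higher in 2 of 18 cases (median -1.11, adjusted p = 0.012 and 0.084), with CXCL8 at -2.61 ± 0.15. Autophagy and lysosome genes were lower in 20 and higher in 12 of 37 cases (median -0.16, adjusted p = 0.019 and 0.066). Interferon-stimulated genes were higher in 13 and lower in 4 of 23 cases (median 0.29, adjusted p = 0.022 and 0.067), with IFIT1 at 2.56 ± 0.12. Apoptosis regulators were lower in 16 and higher in 8 of 31 cases (median -0.40, adjusted p = 0.034 and 0.12), with TNFRSF10B at -2.29 ± 0.04. Stem cell markers were higher in 10 and lower in 6 of 19 cases (11 and 6 adjusted over the list alone; median 0.38, adjusted p = 0.049 and 0.16), with RNF43 at 1.47 ± 0.06 and MSI2 at 0.80 ± 0.03. Where no count adjusted over the list alone is given, it was the same. The stem cell marker call was lost under a stricter low-count filter (adjusted p = 0.058), without GTEA7 replicate 4 (adjusted p = 0.052) and without any GTEA1 library (adjusted p = 0.061, 0.05, 0.055 and 0.076 for replicates 1, 2, 3 and 4), and the apoptosis call without GTEA7 replicate 4 (adjusted p = 0.052) and with library size only (adjusted p = 0.05). The other 10 lists did not pass, with adjusted p from 0.2 (epithelial junction genes) to 0.99 (fibroblast, endothelial and blood cell markers). Among them, median and camera's direction differed in sign for TGF-beta target genes (median 0.15, mean -0.13), xenobiotic response genes (0.33, 0.26) and LXR target genes (-0.13, 0.16).

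The changes of the extracts against DMSO were then set side by side. Of 3349 genes that passed in both, 2422 went the same way and 927 opposite ways. Higher in both were 1279 genes, where independent lists of these sizes would share 768, and lower in both were 1143, where they would share 680. Higher in GTEA1 and lower in GTEA7 were 408 genes (668 for independent lists), and 519 were lower in GTEA1 and higher in GTEA7 (782). Across genes, which are not independent replicates, the log2 fold changes correlated with Pearson's r = 0.311 and Spearman's rho = 0.284. Because both share the 3 DMSO libraries, 20 simulations with no effect of either extract gave r from 0.54 to 0.578. The observed covariance was 0.0821 and the simulated one 0.015 on average (0.0143 to 0.0158), an excess of 0.0671. The simulations drew every library at the DMSO level and filtered genes anew, so genes with few DMSO counts could drop out. The excess therefore estimates the shared effect only roughly and may still hold a part from the shared controls. In these simulations 0 genes passed in both the same way. With 3 control libraries the controls could not be split into parts of at least 2, so part of the excess of shared genes over independent lists may come from the shared controls.

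**Figure D3:**
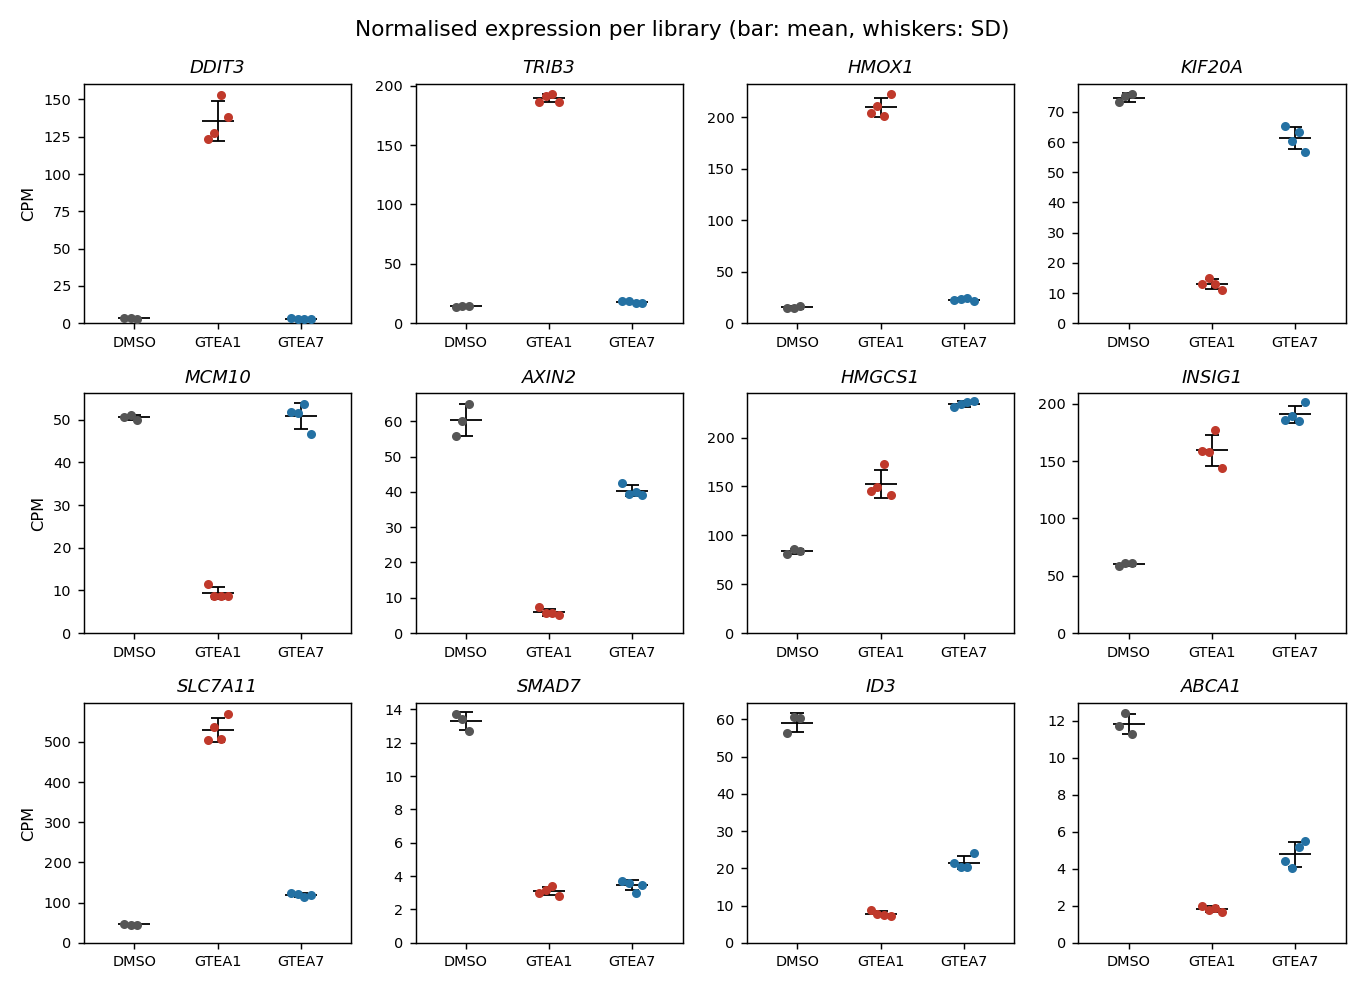
Normalised expression in CPM (vertical axes, starting at 0) of 12 named genes in DMSO, GTEA1 and GTEA7, with 1 point per library, the mean as a bar and the SD as whiskers. DDIT3 and HMOX1 reach 135 and 209 CPM in GTEA1, HMGCS1 is highest in GTEA7 at 235 CPM, and SMAD7 is at 3.1 CPM in GTEA1 and 3.44 CPM in GTEA7 against 13.3 CPM in DMSO.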

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

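The tests of scaling and of histone messages for the mitochondrially encoded genes were chosen after the result was seen. The others were fixed before.

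GTEA1 changed 12895 of 17963 genes, and 3768 of them at least 2-fold. Each other scaling of the libraries gave at least 1.001 times as many genes changed at least 2-fold, and GC content with transcript length accounted for 0.7% of the variance of the log2 fold changes over the 95.1% of genes with these values. The count at 2-fold thus did not hinge on which of these scalings was used. GC content with length is argued against as the whole source of the breadth. Leaving out the TMM factors (mean 1.0542 in DMSO and 0.9443 in GTEA1) shifts fold changes too little to decide such a count. All the scalings are relative, so a change of the total RNA per cell was not tested. The split by extract was the only 1 of 35 to give as many genes, which argues against a chance split of these libraries. With 35 splits the real one can do no more than rank first. Any other difference between the groups would make it rank first too. The highest other count was 8392, from the split of GTEA1 replicate 1 with the 3 DMSO libraries against the other GTEA1 libraries. That split is nearly the real one. An effect of the extract, which the design names, stays open as a hypothesis.

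Among mitochondrially encoded messages in GTEA1, MT-CYB fell from 6600 to 3220 CPM while MT-CO1 rose by 0.28 ± 0.04 on the log2 scale. These 2 members lay 22.2 standard errors apart, which a single scaling factor per library cannot give. The 404 nuclear pseudogenes of these genes went from 1469.5 to 972.2 CPM. Their change was -2.46% of the 20208 CPM that the 9 falling members lost. This argues against the lost reads having been counted for the pseudogenes instead. Both fell, so some reads of the messages may still be counted for these copies, which was not tested. Lower capture of messages with short poly(A) tails may still be the source: the 6 histone genes used as a probe had a median of 0.4 but went both ways, with 2 higher and 1 lower. This and an effect of the extract on individual messages cannot be told apart.

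The extracts moved 927 genes in opposite directions, each past the threshold against DMSO. All of them passed in the direct comparison too, which follows from the opposite calls and is no further support. Higher in GTEA1 and lower in GTEA7 were 408, where independent lists would share 668. The reverse held for 519, where they would share 782, so opposite changes were fewer than for independent lists. Of 14 lists that passed for both extracts, 11 went the same way and 3 opposite ways. For those 3, the direct test gave an adjusted p of 0.0012 for mesenchymal and EMT genes (adjusted p = 0.086 with an estimated correlation), 7.3e-11 for focal adhesion, laminin and migration genes (0.0012) and 3.1e-08 for heat shock genes (0.063). Against DMSO, none of the 3 kept its call in both extracts with an estimated correlation: the adjusted p in GTEA1 and GTEA7 was 0.23 and 0.07 for mesenchymal, 0.0025 and 0.052 for focal adhesion, and 0.1 and 0.28 for heat shock genes. Against DMSO, the split by extract was the only 1 of 35 for GTEA7 as well, with 4036 genes against 1269 for the next. For GTEA7 against GTEA1 it was again 1 of 35, with 13056 against 0 for every other split. Ranking first of 35 argues against a chance split of the libraries for both counts of genes. It does not bear on the opposite directions of the 3 lists, for which chance is not excluded.

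In 20 of 411 groups of 4 values, or 4.9%, a library stood far from the other 3, and chance alone gives about 1 in 20. There were 8 in GTEA1 and 12 in GTEA7, of which 5 in GTEA7 replicate 4. That library had 15.3% of its counts in mitochondrially encoded genes against 15% in the others. In GTEA1, MCM10 (11.4 CPM) and MT2A (332 CPM) were high in replicate 1, ACACB (16.2 CPM) in replicate 2, HES1 (32.3 CPM) in replicate 3 and CDKN1A (377 CPM) in replicate 4. Low values were 0 CPM for MMP7 in replicate 3, and 27.9 CPM for MMP14 and 258 CPM for MSI2 in replicate 4. In GTEA7, high values were MT-CO1 (33900 CPM) in replicate 2, MANF (60.8 CPM) in replicate 3, and XBP1 (60.6 CPM) and SPRY4 (111 CPM) in replicate 4. Low values were LIPG (23.6 CPM) in replicate 1, RNF43 (38.2 CPM), ZNRF3 (36.1 CPM) and ADM (33.6 CPM) in replicate 2, VIM (1.06 CPM) in replicate 3, and SLBP (115 CPM) and CALR (716 CPM) in replicate 4.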

How the results depend on the processing

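Library size only for the lists was chosen after seeing the data. Counts of genes for GTEA1 against DMSO and for GTEA7 against GTEA1 stayed within 1.5 times under every alternative. For GTEA7 against DMSO, library size only gave 1255 genes higher and 2954 lower, no filter 160 changed at least 2-fold, and the DESeq2 Wald test 1146 lower and 58 changed at least 2-fold. The cause was not tested, except that no filter adds genes with few counts. With an estimated correlation 12, 9 and 11 lists passed in GTEA1, GTEA7 and the direct comparison. With fry 32, 22 and 34 of the 35 lists passed, but it tests no list against other genes, and the calls of G2/M and mitosis genes (adjusted p = 0.11) and cytosolic ribosomal protein genes (adjusted p = 0.29) in GTEA7 were lost. Signs turned for NES in GTEA1 with library size only (-0.04), and in GTEA7 for CDKN1A with DESeq2 size factors (0), no filter (0.01) and the DESeq2 Wald test (0.01). The cause was not tested, and of these only NES had passed. Leaving out a library gave from -0.03 to 0.02 for CDKN1A, from -0.06 to 0.4 for SOX2 and from -0.41 to 0.07 for SNAI2 in GTEA7. It gave 12433 to 12860 genes for GTEA1, 2973 to 4470 for GTEA7, 12526 to 13204 for the direct comparison and r from 0.28 to 0.354. With the replicate number as a block the counts were 12725, 4087 and 13016 and r was 0.304; the mesenchymal list in GTEA1 then had an adjusted p of 0.051. Libraries with the same number were not alike (r of their deviations -0.055 to 0.026, against -0.041 to 0.043 for other pairs). This gave no sign of pairing but does not exclude a shared culture or day. Small changes were missed more often: in simulated data 59.7% were found at the smallest fold tried in either comparison, and 82.1% and 88.1% at 1.5-fold for GTEA1 and GTEA7.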

Other observations

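All gene sets in this part, and the test on p53 target genes, were chosen after the data had been seen. For the further BMP and LXR target genes the prediction was written before their values were looked at.

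Cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, rose with GTEA1 in 16 of 20 cases and fell in 3 (median log2 fold change 0.88, adjusted p = 1.5e-18, and adjusted p = 0.032 with an estimated correlation), with SARS1 at 2.10 ± 0.04. With GTEA7, 14 rose and 0 fell (median 0.15, adjusted p = 8.3e-08, and adjusted p = 0.13 with an estimated correlation). The 15 mitochondrial synthetases did not pass in GTEA1 (adjusted p = 0.48). With GTEA7, 21 of 35 proteasome subunits (adjusted p = 1.4e-07, 0.28 with an estimated correlation), 24 of 76 mitochondrial ribosomal proteins, with 2 lower (adjusted p = 0.00026, 0.45), and all 8 subunits of the CCT chaperonin (adjusted p = 2.6e-06, 0.23) rose. With GTEA1 these 3 sets did not pass (adjusted p = 0.84, 0.77 and 0.23). The direct test passed for the chaperonin only (adjusted p = 0.009, 0.45 with an estimated correlation).

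The p53 target list rose with GTEA1, and some of its members are known targets of the ATF4 stress response as well. Without 8 such members, 8 of 22 were higher and 9 lower, with a median of -0.08 and an adjusted p of 0.91. The 8 were picked with their values in view, and 7 of them are among the list's 8 largest rises, so their removal would end the call whatever the reason. Whether p53 or ATF4 activity lies behind their rise cannot be told apart from these data.

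With GTEA7, ID3, SMAD7, DLX2, MSX2 (-0.92 ± 0.06) and ATOH8 were lower, all of them known targets of BMP signalling, and all were lower with GTEA1 too (MSX2 by -2.01 ± 0.07). ID1, a relative of ID3, was not lower with GTEA1: it had 223 ± 5 CPM in DMSO, 252 ± 5.4 in GTEA1 and 169 ± 4.1 in GTEA7. The further genes below were tested for GTEA7 only. Lower BMP pathway output may be the source: of 10 further BMP target genes, 5 fell and 0 rose (unadjusted camera p = 0.0016, and unadjusted p = 0.02 with an estimated correlation), namely SMAD9 (-0.61 ± 0.09), MSX1 (-0.43 ± 0.06), DLX1 (-0.64 ± 0.15), DLX4 (-0.23 ± 0.08) and GATA2 (-0.38 ± 0.07). The other 5 did not pass. Other pathways also act on these genes, and no protein was measured.

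ABCA1, ABCG1 and MYLIP, known LXR targets, were lower with GTEA7 beside higher SREBP2 target genes, so lower LXR output was weighed and may be a source. Of 6 further LXR target genes 1 fell, TMEM135 rose (0.56 ± 0.04), and the median was -0.11. Camera's unadjusted p for this set was 0.52, with its direction higher. The list of LXR target genes fixed before the data were examined did not pass either (adjusted p = 0.52, direction higher), with SCD and SREBF1 among its members that rose. The outcome written beforehand as speaking against it, a p at or above the threshold, was met. That rule was changed after the result, because a missed p over 6 members that go both ways shows no absence. The test decides nothing, and the explanation stays open.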
